A study of Homo sapiens with 16 samples.

How the data were processed

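Gene expression was measured in 16 samples of MCF7 cells, an estrogen-receptor-positive human breast cancer line, on single-colour Agilent oligonucleotide arrays. The labels give 4 groups of 4 samples: a control sub-clone and a sub-clone carrying MKL1ΔN200, each treated for 4 h with ethanol vehicle (EtOH) or with 10 nM estradiol (E2). MKL1ΔN200 is a constitutively active, truncated form of MKL1 (gene symbol MRTFA), a coactivator of the serum response factor SRF. Per the labels' protocols, cells were kept for at least 72 h in medium with 2.5% hormone-stripped serum, tetracycline at 1 µg/mL was given for the last 48 h, and RNA integrity numbers were 9.8 to 10. The labels do not say whether control cells also received tetracycline, and they do not say that the 4 replicates of a group are separate cultures, so the p-values measure only the spread between these samples.

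The deposited scanner files hold a fluorescence intensity per spot on a linear scale, made with Feature Extraction 10.7.1.1 per the file headers. The processed intensity (gProcessedSignal) has the background subtracted by that software, per the file headers. Each array has 62976 spots, of which 61657 are not controls, and the headers name the human build hg19. The deposited series matrix holds log2 values by the authors. They matched log2 of the processed intensity of the same array within 0.005, with values of 1 or less set to 0, so the arrays were not scaled to each other in that table. Its 45207 probes include 1 control, the filter that selected them is not given in the sources used here, and its column medians lay between 6.84 and 7.33. The column medians were 7.21, 7.11, 7.33 and 7.11 for control EtOH replicates 1 to 4, and 7.11, 6.92, 7.31 and 7.33 for control E2. They were 6.87, 6.84, 6.89 and 7.08 for MKL1ΔN200 EtOH replicates 1 to 4, and 6.88, 7.03, 7.01 and 7.03 for MKL1ΔN200 E2.

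For the main values, each array's processed intensities were divided by its 75th percentile over spots that are not controls. A floor of 0.01 of that percentile was set (log2 of -6.64), log2 was taken, spots marked as outliers by the scanner software were left out, and copies of a probe were averaged. One incomplete line at the end of 1 array's file (MKL1ΔN200 E2 replicate 4) was left out. A probe entered the tests when over 50% of its copies were well above background on all 4 arrays of at least 1 group, which left 27914 of 50683 probes. Gene names came from matching RefSeq accessions of the array to a RefSeq table of GRCh38.p14. Of 30878 probes with such an accession, 28174 matched, and 22509 probes kept the identifier of the array. Because the builds differ, no coordinates are given. Where several probes had 1 symbol, the probe with the highest mean over the 16 arrays was used, which gave 22716 tested genes, 15114 of them with a symbol.

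The 5 comparisons were fitted in 1 limma model (3.58.1, R 4.3.3, lmFit and eBayes with default settings) with 4 group means over all 16 arrays, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were E2 against vehicle in each sub-clone, MKL1ΔN200 against control cells under each treatment, and the difference of the E2 effects. For genes in 12 lists, camera (limma, preset correlation of 0.01, two-sided) compared the list with the other genes, adjusted over 60 tests. The lists were estrogen-induced, estrogen-repressed, MRTF-SRF target, luminal, basal-like, mesenchymal, cell cycle, immediate-early and MAPK feedback, ribosome biogenesis, unfolded protein and amino acid stress, interferon response, and stromal and blood cell marker genes. Some genes are on more than 1 list, so the lists are not independent. The groups, comparisons, lists, other settings and the rule for naming genes were set before the data were examined. Overlap between the E2 responses was tested with Fisher's exact test, two-sided. The tests were also tested on simulated data with 22716 genes and known changes. The noise was drawn independently for each gene and array, without the differences by replicate number of the real arrays. The shares recovered may therefore not hold for the real data. False calls numbered 6 to 15 per comparison. Of genes changed 2-fold, 68.7% were recovered for E2 in control cells, 76.1% for E2 in MKL1ΔN200 cells, 85.1% for the clone difference under vehicle, 80.1% for that under E2 and 53% for the difference of the E2 effects. At 4-fold these shares were 92.4%, 89.4%, 89.4%, 93.4% and 78%, and at 1.5-fold 41.8%, 25.4%, 43.3%, 50.2% and 18.7%.

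Named genes are MRTFA and ESR1, the 6 highest and 6 lowest genes with a symbol per comparison whose groups did not overlap and whose adjusted p passed (for the difference of the E2 effects, by adjusted p), up to 4 members per list with the largest change that passed, and fixed genes. The fixed genes were GREB1, TFF1, PGR, CXCL12, MYC and CCND1 for E2, and ACTA2, TAGLN, CNN1, KRT5, KRT18 and GATA3 for the clones. Because many of the largest clone differences were against cells with no measurable signal, the highest and lowest genes measured in both groups were added after the values were seen, as were all other named genes outside this rule. KRT5 and CNN1 did not pass the filter and were not tested. One gene called for E2 in MKL1ΔN200 cells with the replicate block is not reported here. Where a probe was not well above background on any array of a group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. Such a bound holds for the main values only, and other settings gave smaller differences for some genes. Between the clones under vehicle, the log2 differences over all settings were 7.95 to 13.5 for GLYATL1, 3.49 to 8.88 for LMOD1 and -6.69 to -1.76 for CLEC3A.

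The labels number the replicates 1 to 4 in each group, and deviations from the group means were correlated over genes to check whether the numbers pair samples. Same-numbered arrays correlated at 0.57 to 0.87 between the control groups and at 0.13 to 0.73 between the MKL1ΔN200 groups. Arrays of other numbers had means of -0.23 and -0.15. Deviations within a group sum to 0, so these negative means follow from the positive ones and are no separate evidence. The best match had the same number for 3 of 4 arrays within each clone, and for 2 to 4 of 4 in combinations across the clones. Every same-numbered pair in all combinations of groups was at 0.13 or higher, so the numbers were taken to pair samples. The main counts, SEs and p-values nevertheless come from the fit without this block, which was set in advance. Values with the replicate block are given beside them where they change a call. The block raised the genes called for E2 from 461 to 1439 in control cells and from 0 to 4 in MKL1ΔN200 cells.

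The other settings chosen in advance were normexp background correction (offset 50), quantile normalization, median centring, the authors' matrix, no filter on dim probes, a filter over all 16 arrays (23575 probes), a fold minimum of 2, trend and robust variance priors, fits with only the arrays compared, every probe tested, a slide block, a replicate block, leaving out each array, and for lists an estimated correlation and fry. The column of mean signals was not present in the files used, so normexp took the median signal and median background. Settings added after the data were seen were scaling on 10 spike-in (E1A) probes, keeping outlier spots, leaving out replicates 3 and 4 of all groups, leaving out MKL1ΔN200 E2 replicates 2 and 4, and pairing within each clone. The 16 arrays lay on 3 slides, each scanned as a batch of its own, so slide and scan are 1 factor. Control EtOH replicates 1 and 3, control E2 replicate 1, MKL1ΔN200 EtOH replicate 4 and MKL1ΔN200 E2 replicates 2 and 3 were on slide 1. Control EtOH replicate 4, control E2 replicates 2 to 4 and MKL1ΔN200 EtOH replicates 1 to 3 were on slide 2, and the other 3 arrays on slide 3. Within a slide the groups thus held unlike replicate numbers, so within-slide and slide-block values also carry differences by replicate number.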

Results

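Transcript levels were measured in MCF7 T-REx cells, a luminal breast cancer line with a tetracycline-inducible expression system. A control sub-clone was compared with a sub-clone carrying MKL1ΔN200, a constitutively active form of MKL1. Each was treated for 4 h with ethanol vehicle or with 10 nM estradiol (E2), with 4 samples per group and 16 single-colour arrays in all. The 75th percentile of the processed intensity was 433 to 623 per array, and 53% to 62.2% of probes were well above background. The number of arrays limits the precision of every value. Levels are log2 of the intensity over the array's 75th percentile, and differences are log2 differences with their standard error (SE) from limma, with 4 samples per group unless another number is given. One sub-clone stood for each genotype, so differences between the sub-clones belong to these clones.

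The transcript of the expressed gene was examined first. MRTFA, which encodes MKL1, lay at -0.08 ± 0.11 (SD, n = 4) in control cells and 0.81 ± 0.14 in MKL1ΔN200 cells under vehicle. It was 1.85-fold higher in MKL1ΔN200 cells under vehicle (0.89 ± 0.09, adjusted p = 7e-07) and 1.78-fold higher under E2 (0.84 ± 0.09, adjusted p = 1.3e-06). Under E2 it did not pass with median centring (0.41, adjusted p = 0.063) or spike-in scaling (0.21, adjusted p = 0.29). Over all settings it was 0.53 to 0.94 under vehicle and 0.21 to 0.88 under E2. Its single probe does not separate the mutant from the cell's own transcript. ESR1, which encodes estrogen receptor alpha, lay at 1.43 ± 0.19 in control and -0.60 ± 0.24 in MKL1ΔN200 cells under vehicle, a 4.09-fold lower level (-2.03 ± 0.16, adjusted p = 7.2e-08). Under E2 it was 3.26-fold lower (-1.70 ± 0.16, adjusted p = 4.7e-07). Other ESR1 probes gave smaller differences, the smallest being -1.34 under vehicle and -1 under E2.

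Samples within a group differed in a set of genes whose median level rose with the replicate number in all 4 groups. The set held 163 genes, chosen after the values were seen as at least 4 log2 units higher in replicate 4 than in replicate 1 in both control groups. They included VIM (the intermediate filament vimentin), AXL (a receptor kinase), ZEB1 (a transcription factor of mesenchymal cells), SPARC (a matrix protein) and PLAU (urokinase). VIM lay at 0.34, 4.07, 6.29 and 7.05 in control vehicle replicates 1 to 4, and at -1.26, 1.24, 4.79 and 5.98 in the MKL1ΔN200 vehicle samples of the same numbers. The set's median was -4.58, -1.78, 0.52 and 1.02 in the control vehicle samples and -3.75, -2.90, -0.66 and 0.39 in the MKL1ΔN200 vehicle samples. The set held 7 of the 18 tested genes of the mesenchymal list, 4 of the basal-like list, 4 of the immediate-early list and 3 of the MRTF-SRF list. None of the 163 genes was called for E2 in control cells, and 10 were called in each comparison of the clones. The set was chosen for large differences within the control groups, so the test without a block had little power for its genes. These counts do not show that the genes were unaffected.

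**Figure D1:**
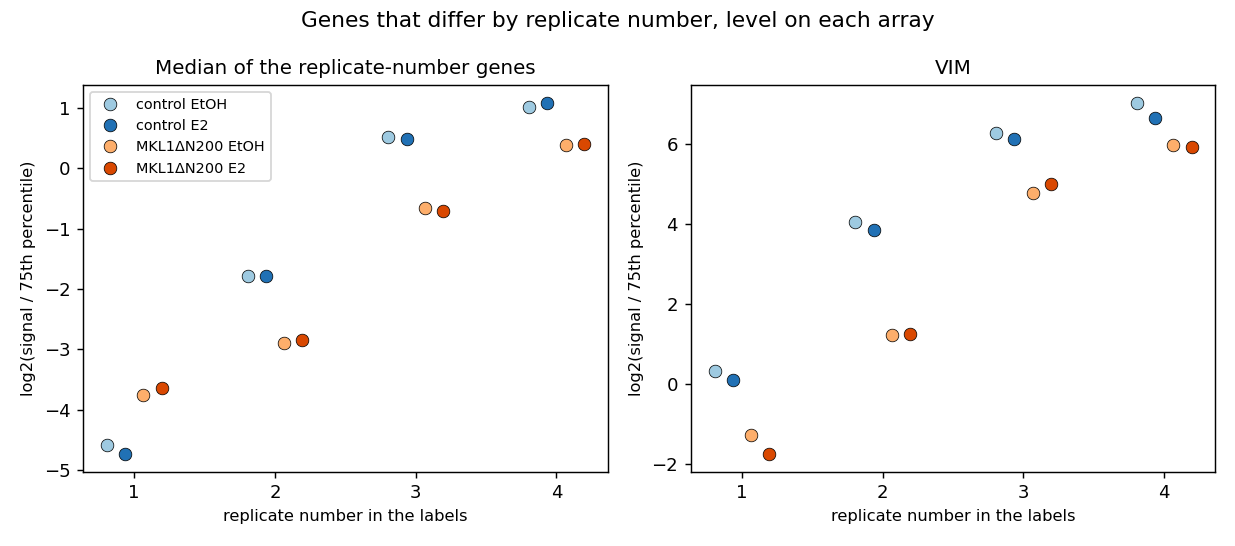
Median level of the 163 genes of the replicate set and level of VIM, as log2 of signal over the array's 75th percentile, by replicate number, with 1 colour per group and 1 point per array. VIM lay at 0.34 in control vehicle replicate 1 and at 7.05 in replicate 4, and at -1.26 and 5.98 in the MKL1ΔN200 vehicle samples of the same numbers.

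The response to E2 in control cells shows which genes the hormone changed within 4 h without the mutant. E2 raised classical estrogen receptor targets and genes of ribosome biogenesis. PGR, the progesterone receptor gene, rose 5.92-fold (2.57 ± 0.14, adjusted p = 9.9e-07), from -4.29 ± 0.24 to -1.72 ± 0.25 (SD, n = 4 each). Over all settings its rise was 1.4 to 2.71. GREB1, which encodes a cofactor of the receptor, rose 4.87-fold (2.28 ± 0.42, adjusted p = 0.0094), and the chemokine gene CXCL12 rose 4.5-fold (2.17 ± 0.26, adjusted p = 0.00047). MYC, the growth-promoting transcription factor gene, rose 2.6-fold (1.38 ± 0.15, adjusted p = 0.00029). TFF1, which encodes a secreted trefoil peptide, did not pass (0.49 ± 0.18, adjusted p = 0.25), from a level of 8.27 ± 0.27 already high under vehicle. CCND1, the cyclin D1 gene, did not pass (0.37 ± 0.10, adjusted p = 0.074), but did with the replicate number as a block (adjusted p = 0.0042). The same holds for ESR1 itself, with -0.37 (adjusted p = 0.37) and an adjusted p of 0.0049 with the block.

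The highest increase was that of EGR3, an early growth response transcription factor, at 14-fold (3.81 ± 0.30, adjusted p = 1.7e-05). Its level on the control vehicle arrays was low (-4.86 to -3.38), and the size of its rise varied with the setting, from 2.28 to 4.1. SMTNL2 (2.86), NEFH (2.78), VXN (2.7), HEY2 (2.57) and PGR were among the next, but SMTNL2, NEFH and HEY2 were well above background on only 2, 1 and 3 of the 4 vehicle arrays. Among genes that fell, RUNX1T1, which encodes a transcriptional corepressor, was 2.5-fold lower (-1.32 ± 0.24, adjusted p = 0.0081) and LIPH, a phospholipase gene, 2.39-fold lower (-1.26 ± 0.20, adjusted p = 0.0039). CCR1, a chemokine receptor gene, fell by 1.24, PPFIA2 by 1.22, the ligand gene WNT11 by 1.18 and the muscarinic receptor gene CHRM1 by 1.12, and the dopamine receptor gene DRD1 was at least 1.88-fold lower (adjusted p = 0.0043). PPFIA2 (adjusted p = 0.023) did not pass without control EtOH replicate 2, 3 or 4 or control E2 replicate 1 (up to 0.075), and CHRM1 did not pass with a slide block (adjusted p = 0.1, 0.00032 to 0.25 over all settings).

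Of the 50 estrogen-induced genes, 31 rose and none fell (39 adjusted over the list alone), with a median of 1.06 and a camera adjusted p of 9.3e-58 (0.0017 with an estimated correlation). Besides PGR and GREB1 they included RAPGEFL1 (5.21-fold) and MYB (3.05-fold), and, chosen after their values were seen, SGK3 (1.84), CA12 (1.72) and STC2 (1.45). Of the 24 ribosome biogenesis genes, 15 rose and none fell (20 adjusted over the list alone), with a median of 0.52 and a camera adjusted p of 1.2e-34 (0.00031 with an estimated correlation). RRS1, a ribosome assembly factor gene, rose 2-fold (1.00 ± 0.11), and POLR1B, which encodes a subunit of RNA polymerase I, rose 1.86-fold (0.90 ± 0.09, adjusted p = 9.5e-05). NOP16 and NOP2, genes of nucleolar proteins, rose by 0.89 and 0.78. The medians of the estrogen-induced list within slides 1 and 2 were 1.06 and 1.17, and those of the ribosome biogenesis list were 0.42 and 0.42.

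Of the 20 estrogen-repressed genes, TGFB3 (-0.75 ± 0.11, adjusted p = 0.0026) and TP53INP1 (-0.88 ± 0.21, adjusted p = 0.047) fell and KLF4 rose (0.50 ± 0.12, adjusted p = 0.049). Adjusted over the list alone, 7 fell and 1 rose, as with the replicate block. TP53INP1 and KLF4 were each lost without any of 6 arrays. These were control EtOH replicates 1, 2 and 3 for both, control E2 replicates 2, 3 and 4 for TP53INP1 (adjusted p up to 0.16), and control E2 replicates 1, 2 and 3 for KLF4 (up to 0.15). Of 25 other settings, including each array left out, 14 lost the call of TP53INP1 and 13 that of KLF4 (limma adjusted p up to 0.35 and 0.22). The list's median was -0.48 (adjusted p = 2e-05, but adjusted p = 0.17 with an estimated correlation), and -0.37 and -0.18 within slides 1 and 2. In the luminal list, 4 of 31 genes rose, 5 adjusted over the list alone, and with the replicate block 5 rose and 2 fell. The 4 were PGR, MYB, XBP1, a transcription factor gene of secretory cells (1.32 ± 0.26, adjusted p = 0.013), and BCL2, a survival gene (0.65 ± 0.08). All 4 are also on the estrogen-induced list. XBP1 did not pass without control E2 replicate 3 (adjusted p = 0.05) or with a slide block (0.078, 0.002 to 0.17 over all settings). The luminal list's median was 0.01 and its mean 0.24 (adjusted p = 0.0097, but adjusted p = 0.58 with an estimated correlation and 0.088 without control E2 replicate 2), and 0.17 and 0.16 within slides.

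In the immediate-early and MAPK feedback list, FOS (1.63 ± 0.22), EGR3 and MYC (both also on the estrogen-induced list) rose among 28 genes. Adjusted over this list alone 4 rose, and with the replicate block 6. Its median was 0.05 (adjusted p = 0.014, but adjusted p = 0.49 with an estimated correlation and 0.54 with a slide block), and it was -0.24 and -0.09 within slides 1 and 2. This call was also lost without control EtOH replicate 1 (adjusted p = 0.47), control E2 replicate 3 (0.2) or control E2 replicate 4 (0.11). Single members of other lists rose: FOXC1, a transcription factor gene of basal-like tumours (1.21 ± 0.12, adjusted p = 9.8e-05), and the endothelial marker gene VWF (1.97 ± 0.24, adjusted p = 0.00055), whose other probe gave -0.27. No shift was called for the MRTF-SRF (0.95), basal-like (0.41), mesenchymal (0.54), unfolded protein (0.32) and stromal (0.46) lists, the values being camera adjusted p. The cell cycle list (adjusted p = 0.18) passed without control EtOH replicate 4 (0.0054) or control E2 replicate 2 (0.0042). The interferon list (median -0.17, adjusted p = 0.19) passed with a slide block (0.0011) and without control EtOH replicate 1 (0.00011) or control E2 replicate 3 (0.011).

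In all, limma called 461 of 22716 genes for E2 in control cells, 399 higher and 62 lower, at an adjusted p below 0.05. Of these, 114 changed at least 2-fold, 101 of them up and 13 down. With the replicate block, 1439 genes passed (1045 higher, 394 lower), all 461 among them, and with a slide block 228 passed (201 higher, 27 lower), 216 of them among the 461. The count was 300 without control EtOH replicate 2, 290 without control EtOH replicate 3, 284 without control E2 replicate 2 and 283 without control E2 replicate 3. Centring on the array median gave 156 genes, 151 higher and 5 lower (96.8% higher against 86.6% in the main values), and moved the median of all genes from -0.039 to 0.102.

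**Figure D2:**
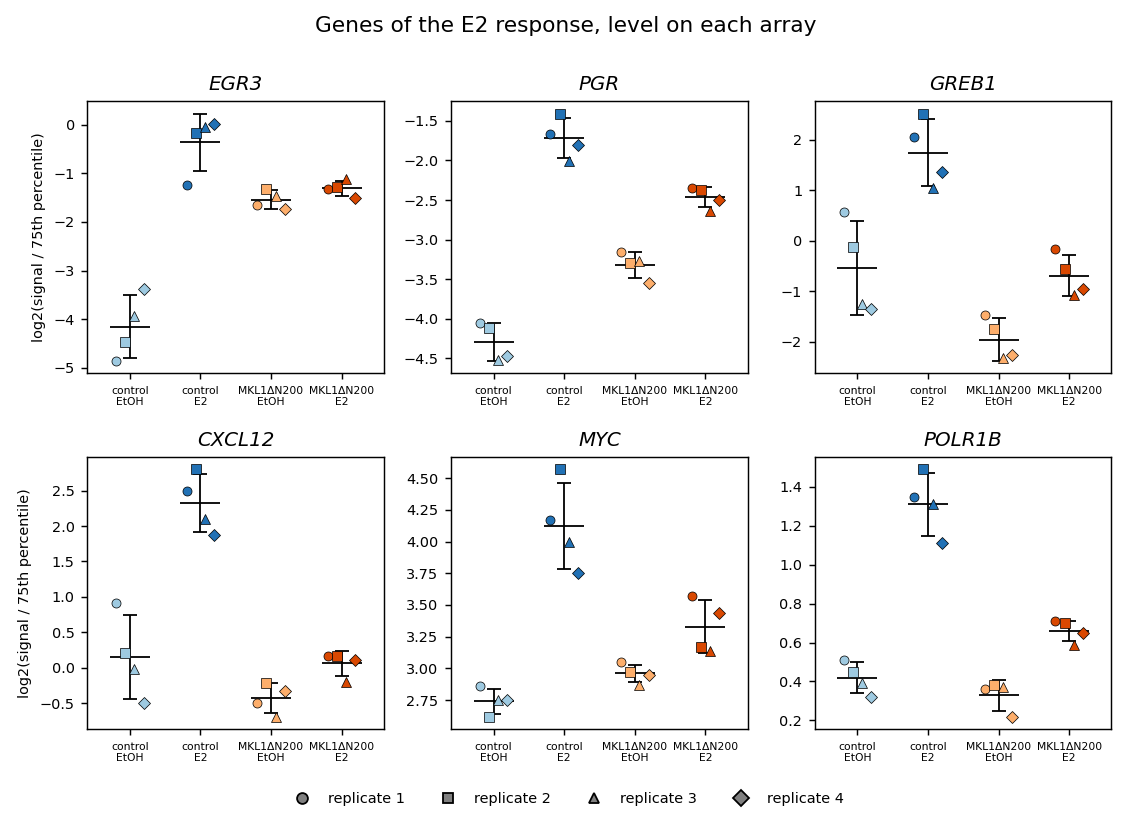
Levels of EGR3, PGR, GREB1, CXCL12, MYC and POLR1B in the 4 groups, as log2 of signal over the array's 75th percentile, with points for arrays (marker shape by replicate number) and bars for mean ± SD (n = 4). PGR lay at -4.29 and -1.72 in control cells under vehicle and E2, and at -3.32 and -2.46 in MKL1ΔN200 cells.

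The same treatment in MKL1ΔN200 cells shows what E2 changed in cells with the active mutant. The estrogen-induced and ribosome biogenesis lists shifted upward there too, by smaller amounts. Without the replicate block, no single gene passed the test over all genes. PGR had 0.86 ± 0.14 (1.81-fold, adjusted p = 0.33), and passed with the replicate block (adjusted p = 0.014, 0.014 to 1 over all settings). GREB1 had 1.27 ± 0.42 (2.4-fold, adjusted p = 1, 0.12 to 1 over all settings), with levels of -1.95 ± 0.42 under vehicle and -0.69 ± 0.41 under E2. CXCL12 had 0.49 ± 0.26, MYC 0.37 ± 0.15, TFF1 0.27 ± 0.18 and CCND1 0.14 ± 0.10, each with an adjusted p of 1. With the replicate block, limma called 4 genes, among them MYB, a transcription factor gene (1.14), NXNL2 (0.83) and PGR. MYB and NXNL2, chosen after their values were seen, had 1.61 and 1.02 in control cells. Without the block limma called 0 genes, where 506 had an unadjusted p below 0.05, and 1 gene passed without MKL1ΔN200 E2 replicate 4.

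The estrogen-induced list had a median of 0.24 in MKL1ΔN200 cells (camera adjusted p = 3.8e-18, 0.046 with an estimated correlation). Adjusted over the list alone, 5 of its 50 genes rose, and with the replicate block 2 passed over all genes. The ribosome biogenesis list had a median of 0.13 (adjusted p = 7.5e-10, 0.016 with an estimated correlation), with 2 genes up adjusted over the list alone. Within slide 1, the only slide with both MKL1ΔN200 groups, these medians were 0.37 and 0.08. The estrogen-repressed list had a median of -0.14 (adjusted p = 0.00037, but adjusted p = 0.26 with an estimated correlation), and -0.07 within slide 1. The MRTF-SRF list had a median of -0.06 (adjusted p = 0.015, but adjusted p = 0.49 with an estimated correlation) and 0.17 within slide 1, and with a slide block the shift turned upward (0.015). It was lost without MKL1ΔN200 EtOH replicate 2 (0.25), E2 replicate 3 (0.075) or E2 replicate 4 (0.071).

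No shift was called for the other 8 lists in the main values. Of these, the luminal list (median -0.04, adjusted p = 0.37) had 2 genes up adjusted over the list alone and 2 with the replicate block. The cell cycle list passed without MKL1ΔN200 EtOH replicate 4 (0.025) or E2 replicate 2 (2.9e-06), and in the other direction without EtOH replicate 2 (0.0074) or E2 replicate 4 (0.00012). The interferon list passed without EtOH replicate 1 (0.016) and the mesenchymal list without E2 replicate 4 (0.043). With a slide block the immediate-early (0.0011) and interferon (0.033) lists passed.

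The genes called in control cells moved mostly in the same direction in MKL1ΔN200 cells, and less far. Of the 399 genes that rose in control cells, 358 (89.7%) had a positive value in MKL1ΔN200 cells, against 47.7% of all tested genes. Their median was 0.67 in control and 0.13 in MKL1ΔN200 cells (camera p = 1.5e-33 in MKL1ΔN200 cells, 0.0061 with an estimated correlation). Of the 62 that fell, 53 (85.5%) had a negative value, with medians of -0.72 and -0.14 (camera p = 3e-13, 0.0043 with an estimated correlation). Together, 411 of 461 (89.2%) had the same sign. The share was 82.4% within slide 1, 79.8% of 228 genes with a slide block, 63.5% of 156 with median centring and 63% of 162 with spike-in scaling, which moved the median of all genes for E2 in MKL1ΔN200 cells to -0.183 and -0.187. The 4 genes called in MKL1ΔN200 cells with the replicate block were all among the 1045 raised in control cells, where 0.18 would be there by chance (Fisher's exact test, two-sided, p = 4.5e-06).

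The difference of the E2 effects tests whether the hormone response itself differed between the clones. EGR3 and PGR responded less in MKL1ΔN200 cells, and the estrogen-induced list as a whole did too. EGR3 rose by 3.81 in control cells and had 0.24 in MKL1ΔN200 cells, a difference of -3.57 ± 0.42 (adjusted p = 0.0043), and its vehicle level was higher in MKL1ΔN200 cells (-1.55 ± 0.19 against -4.17 ± 0.64). PGR rose by 2.57 and had 0.86, a difference of -1.71 ± 0.20 (adjusted p = 0.0043). FOXC1 had 1.21 and 0.00 (-1.21 ± 0.16, adjusted p = 0.011). SGK3, a kinase gene, had 1.84 and 0.71 (-1.13, adjusted p = 0.03), and SIAH2, a ubiquitin ligase gene, 1.08 and 0.04 (-1.03, adjusted p = 0.044). GAB2, an adaptor protein gene chosen after its values were seen, had 0.89 and -0.02 (-0.91, adjusted p = 0.0044).

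Of the 10 genes called by limma, 8 were lower and 2 higher, and 1718 had an unadjusted p below 0.05. The 4 others were at or near background: RFPL1S (-2.25 ± 0.31, adjusted p = 0.012) and the transcript ENST00000420912 (-1.98, adjusted p = 0.0015) were well above background only in control E2 samples. NR_036581 (1.84, adjusted p = 0.0043) was so only in control vehicle samples, and CSMD3 (1.01, adjusted p = 0.0044) only in control cells. The unnamed transcripts were chosen after their values were seen. SGK3 kept its call only without control EtOH replicate 4, control E2 replicate 1 or MKL1ΔN200 E2 replicate 1 (adjusted p up to 0.096 without each of the 13 other arrays). SIAH2 kept it only without control EtOH replicate 1, control E2 replicate 4 or MKL1ΔN200 EtOH replicate 4 (up to 0.14).

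With the replicate block, 87 genes passed (12 higher, 75 lower), the same 10 among them. With a slide block 1 gene passed, NR_036581 (0.025); EGR3 then had -2.43 and PGR -1.80 (both adjusted p = 0.21), and FOXC1 -0.90 (0.89). Over all settings the adjusted p was 0.00065 to 0.27 for EGR3 and 0.00098 to 0.26 for PGR, with differences of -3.89 to -2.08 and -2.03 to -0.97. Leaving out control E2 replicate 1 gave 17 genes. The share of higher calls was 20% in the main values, 10% with median centring, 8.3% with spike-in scaling and 0% with normexp and the authors' matrix, among 10 to 12 genes each. Median centring and spike-in scaling moved the median of all genes to -0.298 and -0.243.

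The estrogen-induced list had a median difference of -0.70 between the clones' E2 effects (camera adjusted p = 2.9e-35, 0.011 with an estimated correlation). Of its 50 genes, 4 were lower, 24 adjusted over the list alone and 11 with the replicate block, and none was higher. The ribosome biogenesis list had a median of -0.41 (adjusted p = 2.1e-22, 0.0014 with an estimated correlation). None of its 24 genes was called, 13 were lower adjusted over the list alone, and 4 were lower with the replicate block. Within slide 1 the medians of the E2 effects were 1.06 in control and 0.37 in MKL1ΔN200 cells for the estrogen-induced list, and 0.42 and 0.08 for the ribosome biogenesis list.

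EGR3 was the only immediate-early gene and PGR the only luminal gene called for the difference, and both are also on the estrogen-induced list. The immediate-early (median -0.15, adjusted p = 0.0023), luminal (-0.06, 0.015) and estrogen-repressed (0.36, 0.031) lists also differed in the E2 effect. With an estimated correlation these calls were lost, at adjusted p = 0.39, 0.61 and 0.51, and with a slide block at 0.43 (with the direction turned), 0.14 and 0.27. The immediate-early call was lost without control EtOH replicate 1 (0.15). The luminal call was lost without control EtOH replicate 4 (0.053), control E2 replicate 2 (0.1) or MKL1ΔN200 E2 replicate 4 (0.086). The estrogen-repressed call was lost without control EtOH replicate 2 (0.18), control E2 replicate 1 (0.11) or 4 (0.098), MKL1ΔN200 EtOH replicate 4 (0.15) or MKL1ΔN200 E2 replicate 4 (0.071). For the other 7 lists no difference was called in the main values, but the interferon (0.00016), mesenchymal (0.032) and MRTF-SRF (0.0026) lists passed with a slide block. Some passed without a single array. These were the cell cycle list without control EtOH replicate 4 (0.017), control E2 replicate 2 (0.014), MKL1ΔN200 EtOH replicate 2 (0.007) or MKL1ΔN200 E2 replicate 4 (0.00078), and the basal-like list without control EtOH replicate 3 (0.015) or control E2 replicate 1 (0.029). The unfolded protein list passed without control EtOH replicate 4 (0.029) or MKL1ΔN200 E2 replicate 3 (0.049), the MRTF-SRF list without control EtOH replicate 4 (0.024), and the interferon list without control EtOH replicate 1 (0.0024).

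The comparison of the clones under vehicle shows the state of MKL1ΔN200 cells without added hormone. MRTF-SRF target genes, the keratin genes KRT14, KRT16 and KRT17 and interferon-response genes were higher, while cell cycle genes, the prolactin receptor gene and ESR1 were lower. The interferon and cell cycle lists did not pass with an estimated correlation (adjusted p = 0.17 and 0.29). ACTA2, smooth muscle actin, lay at -1.16 ± 0.46 in control and 9.32 ± 0.15 in MKL1ΔN200 cells (SD, n = 4 each), 1430-fold higher (10.49 ± 0.24, adjusted p = 8.7e-14). TAGLN, the actin-binding protein transgelin, was 214-fold higher (7.74 ± 0.20, adjusted p = 1.3e-12). KRT14 and KRT17 were not well above background on any control array and were at least 6800-fold and at least 6810-fold higher in the main values. Over all settings their log2 differences were 10.01 to 14.69 and 10.28 to 13.78. PRLR, the prolactin receptor gene, was 16.8-fold lower (-4.07 ± 0.17, adjusted p = 8.8e-11). GATA3, a luminal transcription factor gene, was lower (-0.87 ± 0.15, adjusted p = 0.00018). KRT18, a luminal keratin gene, did not differ past the threshold (0.15 ± 0.10, adjusted p = 0.25), was called with the replicate block (0.048), and turned to -0.26 with quantile normalization.

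Besides KRT14 and KRT17, the highest genes were the keratin gene KRT16 (at least 2590-fold), the keratin pseudogene KRT16P2 (11.99 ± 0.35, well above background on 1 of 4 control arrays), the cadherin gene CDH16 (at least 2310-fold) and GLYATL1 (at least 1670-fold). KRT14, KRT16 and KRT17 are distinct genes, but they and their pseudogenes are similar in sequence, so their signals are not taken as fully separable. The levels of the 3 KRT14 probes in MKL1ΔN200 cells ranged from -3.95 to 7.22, and the KRT17 probe also lay at 7.22. Among named genes well above background on all 4 arrays of each clone, the highest were MYL7 (a myosin light chain, 11.01), ACTA2, MYLK (myosin light chain kinase, 10.13) and the natriuretic peptide gene NPPB (10.09). The lowest named genes were ATP6V0A4, a proton pump subunit gene (-6.40 ± 0.30, 84.5-fold lower), CSTA, a protease inhibitor gene (-6.07 ± 0.26, 67.2-fold lower), and ABCA12, a lipid transporter gene (-6.01 ± 0.23, 64.5-fold lower, well above background on 2 of 4 MKL1ΔN200 arrays). APOBR, CLEC3A and C9orf152 were at least 20.9-fold, at least 14.8-fold and at least 25.9-fold lower.

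Of the 35 MRTF-SRF target genes, 32 were higher and none lower, with a median of 2.86 (camera adjusted p = 3.7e-16, 0.012 with an estimated correlation). They included ACTG2, another muscle actin gene (9.88 ± 0.57), LMOD1 (at least 48.2-fold) and, chosen after their values were seen, SRF itself (3.37), TPM1 (4.49) and VCL (2.52). The list's medians within slides 1 and 2 were 2.79 and 2.55. Of 35 cell cycle genes, 33 were lower and none higher, with a median of -1.66 (adjusted p = 2e-12, but adjusted p = 0.29 with an estimated correlation). CDT1 (-2.31 ± 0.21), MCM2 (-2.21 ± 0.20, 4.62-fold lower, adjusted p = 2.6e-07), MCM10 (-2.09) and CCNB2 (-2.07) were lower; the first 3 act in licensing and starting DNA replication, and CCNB2 encodes a mitotic cyclin. The medians within slides 1 and 2 were -1.17 and -2.07.

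Of 21 interferon-response genes, 20 were higher and none lower, with a median of 3.19, or 3.14 with dim genes at their bounds (adjusted p = 4.3e-10, but adjusted p = 0.17 with an estimated correlation). IFIT1, an antiviral protein gene, was 35.7-fold higher (5.16 ± 0.51, adjusted p = 7.9e-07), IFI44L (well above background on 3 of 4 control arrays) was higher by 5.16 ± 0.66, and OAS1, which encodes an enzyme that senses double-stranded RNA, by 4.75 ± 0.32. RIGI, which encodes a sensor of viral RNA, was higher by 5.04 ± 0.32, and its other probe gave 0.69. The medians within slides 1 and 2 were 3.63 and 2.79. Of 28 immediate-early and MAPK feedback genes, 17 were higher and 2 lower (median 1.11, adjusted p = 0.00027, but adjusted p = 0.27 with an estimated correlation; 1.69 and 0.96 within slides). EGR4 was 120-fold higher (6.91 ± 0.32), and DUSP5, PHLDA1 and EGR3 were higher by 3.42 ± 0.85, 3.14 ± 0.40 and 2.62 ± 0.30.

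Of 21 basal-like genes tested, 11 were higher and 1 lower, and with the replicate block 12 higher and 4 lower, with a median of 2.36 (adjusted p = 4.4e-05, 0.02 with an estimated correlation; 2.94 and 2.18 within slides 1 and 2). With the keratins, SERPINB5, the serine protease inhibitor maspin, was 53-fold higher (5.73 ± 0.31; 3 of 4 control arrays well above background). CAV1, the main protein of caveolae (4.75), LAMC2, a laminin chain (3.51), and FOXC1 (2.88) were also higher, chosen after their values were seen. Of 18 mesenchymal genes, 7 were higher and none lower, with no shift of the list (median 0.08, adjusted p = 0.19), and with the replicate block 8 were higher and 6 lower. FN1, fibronectin, was 26.2-fold higher (4.71 ± 0.21). COL5A1 (2.52 ± 0.44), SNAI2 (2.33 ± 0.34, well above background on 2 of 4 control arrays) and TGFB2 (2.26 ± 0.32) were higher. This list's median was 1.66 within slide 1 and -0.96 within slide 2, and it and the basal-like list hold 7 and 4 of the genes that followed the replicate number.

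Of 31 luminal genes, 17 were lower and 8 higher, and with the replicate block 17 lower and 13 higher, with a median of -0.49 (adjusted p = 0.039, but adjusted p = 0.66 with an estimated correlation, 0.098 with the replicate block and 0.098 without MKL1ΔN200 EtOH replicate 4; -0.75 and -0.21 within slides). Besides PRLR, SPDEF, a luminal transcription factor gene (-2.96 ± 0.17), TFF3 (-2.30 ± 0.20) and the receptor gene ERBB3 (-2.09 ± 0.25) were lower. Among the higher members were the adhesion gene CDH1 (1.30) and FOXA1 (0.45, adjusted p = 0.014), chosen after their values were seen. Of 20 estrogen-repressed genes, 13 were lower and 4 higher, with a median of -0.74 (adjusted p = 0.014, but adjusted p = 0.48 with an estimated correlation; -0.85 and -0.51 within slides). PSCA (-2.82 ± 0.35), YPEL3 (-2.74 ± 0.19) and IL1R1, an interleukin receptor gene (-3.25 ± 0.43), were lower, and GADD45A, a stress-response gene, was higher (3.30 ± 0.18).

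The estrogen-induced list moved both ways under vehicle: 18 of 50 genes were higher and 19 lower, with a median of -0.28, a mean of 0.38 and a camera adjusted p of 0.96. The growth factor gene AREG was 75.8-fold higher (6.24 ± 0.39), KRT13 60.7-fold higher (5.92 ± 0.25) and FHL2 28.3-fold higher (4.82 ± 0.25), while GREB1 was lower (-1.42, adjusted p = 0.011). Ribosome biogenesis genes (6 higher, 5 lower of 24, adjusted p = 0.94), unfolded protein and amino acid stress genes (8 higher, 7 lower of 19, adjusted p = 0.94) and stromal markers (2 higher, none lower of 6, adjusted p = 0.53) showed no shift. In these, WDR12 was higher (1.91 ± 0.12), PHGDH (-1.99), XBP1 (-1.43) and DDIT4 (-1.32) were lower, and the monocyte marker gene CD14 was higher (1.17). NOLC1 (-0.63, adjusted p = 0.041) was lost without control EtOH replicate 3 or 4 or MKL1ΔN200 EtOH replicate 1, 2 or 3 (up to 0.12).

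In all, limma called 12156 of 22716 genes under vehicle (53.5%), 6222 higher and 5934 lower, and 5319 changed at least 2-fold, 2961 up and 2358 down. A slide block gave 11616 genes. The split depended on the scaling. Higher calls made up 51.2% in the main values, 30.4% with the authors' matrix (3932 of 12928) and 27.6% with spike-in scaling (3320 of 12010), where the median of all genes moved from 0.01 to -0.286 and -0.347.

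**Figure D3:**
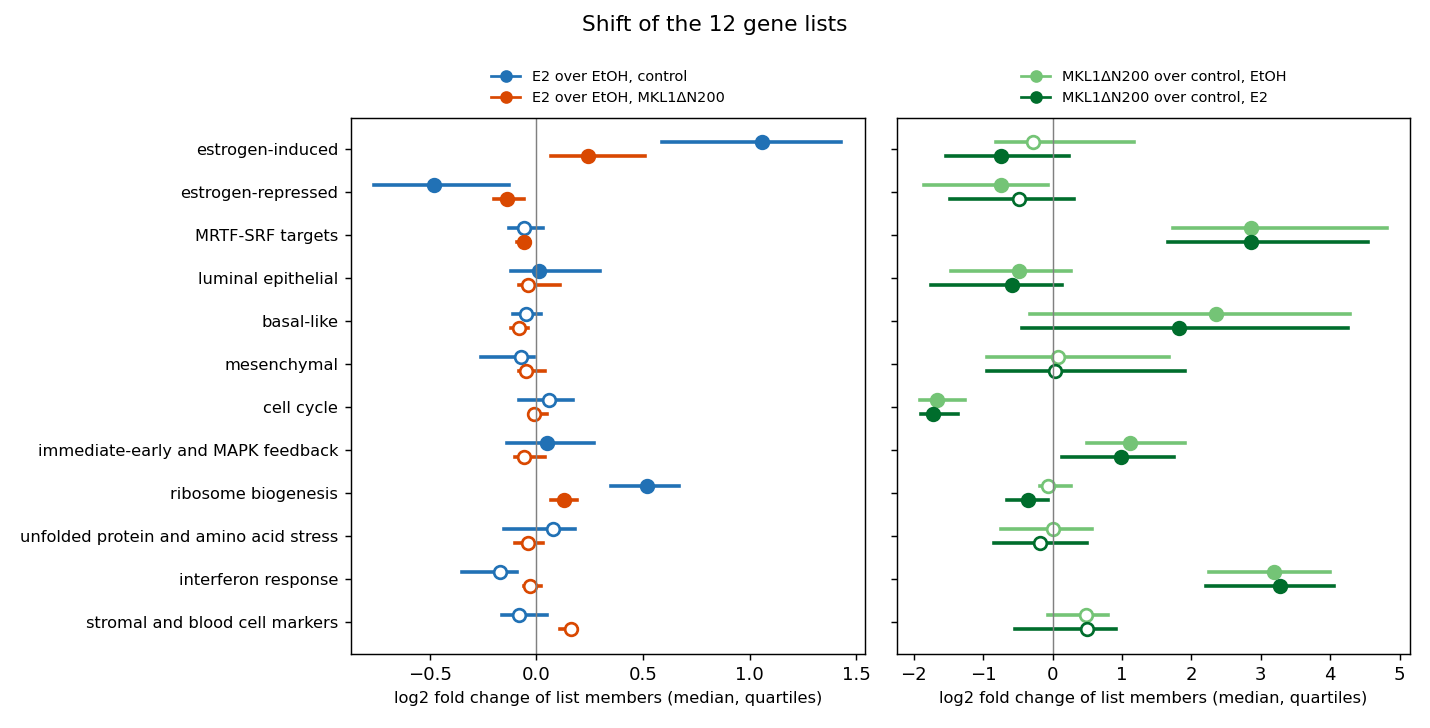
Median log2 difference of each of the 12 gene lists for E2 in each clone and between the clones under each treatment. Bars show the quartiles over tested genes, and points are filled where the camera adjusted p was below 0.05. The MRTF-SRF list had a median of 2.86 in both comparisons of the clones, and the estrogen-induced list 1.06 for E2 in control cells and 0.24 in MKL1ΔN200 cells.

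**Figure D4:**
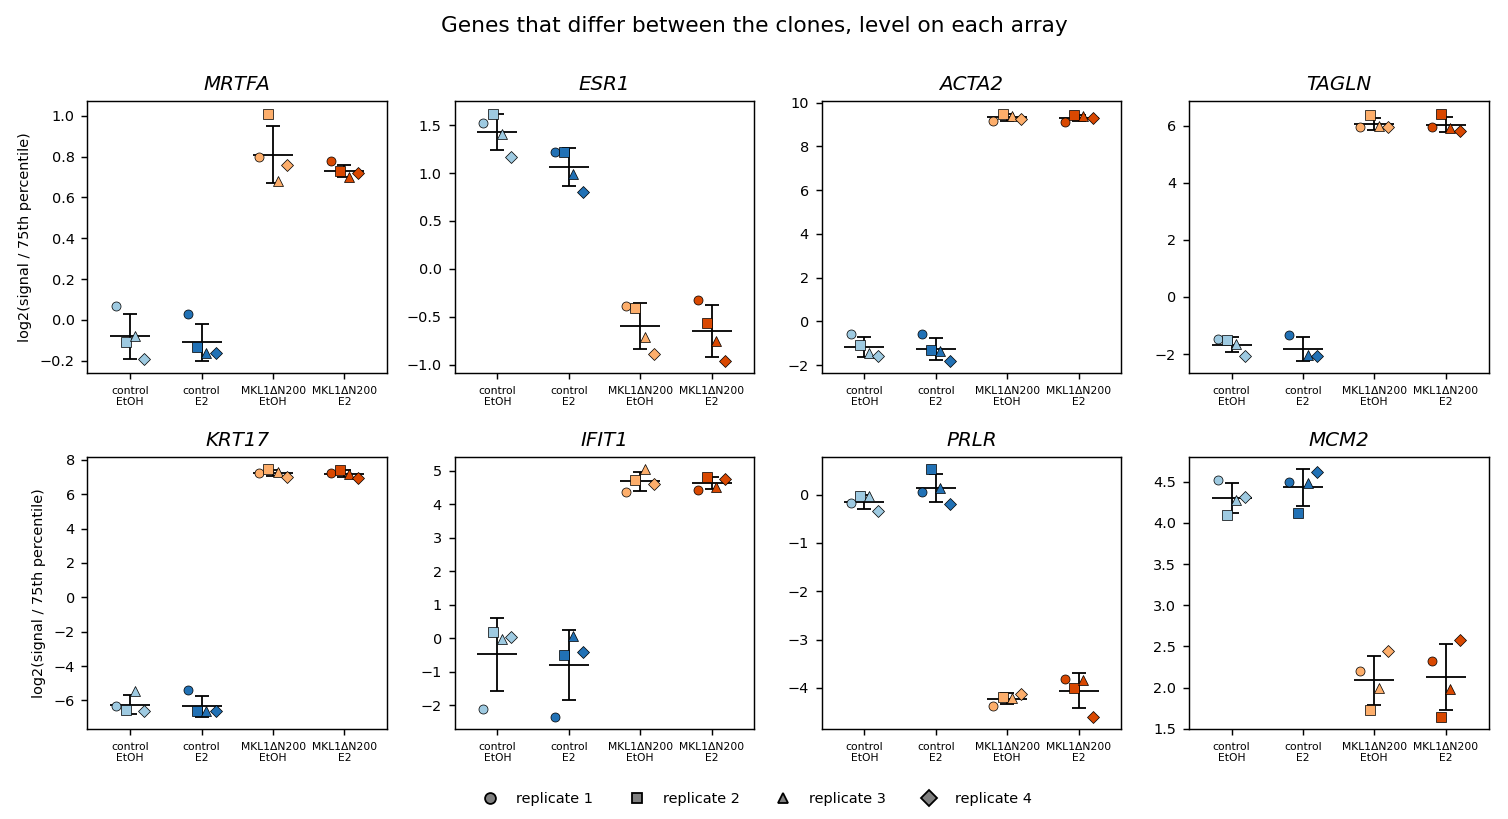
Levels of MRTFA, ESR1, ACTA2, TAGLN, KRT17, IFIT1, PRLR and MCM2 in the 4 groups, as log2 of signal over the array's 75th percentile, with points for arrays and bars for mean ± SD (n = 4; n = 3 for TAGLN in control E2). ACTA2 lay at -1.16 and 9.32 in control and MKL1ΔN200 cells under vehicle, and control values of KRT17 are not above background.

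Under E2, the comparison of the clones shows the same state with hormone present. The MRTF-SRF, keratin, interferon and cell cycle differences were of similar size, and most estrogen-induced and ribosome biogenesis genes were lower in MKL1ΔN200 cells. The interferon, cell cycle, estrogen-induced and ribosome biogenesis lists did not pass with an estimated correlation (adjusted p = 0.19, 0.29, 0.51 and 0.24). ACTA2 was 1520-fold higher (10.57 ± 0.24, adjusted p = 7.8e-14) and TAGLN 232-fold higher (7.86 ± 0.21; 3 control samples). KRT14, KRT17 and KRT16 were at least 7130-fold, at least 6940-fold and at least 2580-fold higher. PRLR was 18.3-fold lower (-4.19). GATA3 was lower (-0.92, adjusted p = 1e-04), and KRT18 had 0.12 (adjusted p = 0.31), which turned to -0.28 with quantile normalization and -0.50 with spike-in scaling. CDH16, GLYATL1 and KRT42P were at least 2460-fold, at least 1700-fold and at least 2120-fold higher. KRT16P2, well above background on 1 of 4 control arrays, was higher by 12.13. Of named genes well above background on all 4 arrays of each clone, MYL7 (11.03), ACTA2, ACTG2 (10.11), NPPB (10.11) and the carbonic anhydrase gene CA14 (10.09 ± 0.35) were highest. ATP6V0A4 (-6.46), ABCA12 (-6.10, well above background on 1 of 4 MKL1ΔN200 arrays) and CSTA (-5.56) were the lowest named genes.

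Of the 50 estrogen-induced genes, 31 were lower and 11 higher under E2, with a median of -0.75 (camera adjusted p = 0.0016, but adjusted p = 0.51 with an estimated correlation; -0.94 within slide 1). MYBL1 (-2.54), GREB1 (-2.43), SGK3 (-2.42) and CXCL12 (-2.26) were lower, and AREG (4.97), KRT13 (4.74) and FHL2 (4.50) higher. GREB1, SGK3 and CXCL12 were chosen after their values were seen. Of the 24 ribosome biogenesis genes, 15 were lower and 2 higher, with a median of -0.35 (adjusted p = 0.0019, but adjusted p = 0.24 with an estimated correlation; -0.47 within slide 1). NOLC1 (-0.96), NOP56 (-0.85) and RRP9 (-0.80) were lower and WDR12 (1.30) higher, and NOP56 did not pass with a slide block (0.12, 0.00012 to 0.12 over all settings).

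The MRTF-SRF list had 32 of 35 genes higher and a median of 2.86 (adjusted p = 2.5e-14, 0.016 with an estimated correlation; 3.28 within slide 1). The cell cycle list had 33 of 35 lower, 34 adjusted over the list alone, and a median of -1.72 (adjusted p = 7.1e-13, but adjusted p = 0.29 with an estimated correlation; -1.80 within slide 1). CDT1 (-2.56), MCM2 (-2.30) and GINS2 (-2.04) were examples. In the interferon list 19 of 21 were higher, with a median of 3.27, or 3.03 with dim genes at their bounds (adjusted p = 2.9e-09, but adjusted p = 0.19 with an estimated correlation; 4.07 within slide 1), among them IFIT1 (42.9-fold) and OAS1 (4.94). In the basal-like list 11 of 21 were higher and none lower, and with the replicate block 12 were higher and 5 lower (median 1.82, adjusted p = 0.00029, 0.037 with an estimated correlation; 3.02 within slide 1). The mesenchymal list had 7 of 18 higher and none lower, with the replicate block 7 higher and 6 lower, and no shift (median 0.04, adjusted p = 0.23; 1.51 within slide 1).

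The luminal list had 19 of 31 lower and 5 higher (median -0.58, adjusted p = 0.0016, but adjusted p = 0.51 with an estimated correlation; -0.61 within slide 1), with SPDEF (-2.83), AGR3 (-2.60) and TFF3 (-2.24) among the lower. The immediate-early list had 15 of 28 higher and 5 lower (median 0.98, adjusted p = 0.031, but adjusted p = 0.51 with an estimated correlation; 1.97 within slide 1), with EGR4 (7.06) and ATF3 (2.40) higher and EGR3 lower (-0.95, adjusted p = 0.013). That call was lost without control E2 replicate 1 (0.1) or MKL1ΔN200 E2 replicate 4 (0.058). The estrogen-repressed (4 higher, 12 lower of 20, adjusted p = 0.073), unfolded protein (8 higher, 8 lower of 19, adjusted p = 0.53) and stromal (3 higher, 1 lower of 6, adjusted p = 0.81) lists showed no shift. Of the stromal and blood markers, CD14 (1.08), CD3E and PTPRC were higher and VWF lower. The calls of CD3E and PTPRC were lost with a slide block (0.36 and 0.24). CD3E was also lost without control E2 replicate 3 or MKL1ΔN200 E2 replicate 2 (up to 0.089), and PTPRC without control E2 replicate 2 or 3 or MKL1ΔN200 E2 replicate 1 or 2 (up to 0.083).

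In all, limma called 14048 of 22716 genes under E2 (61.8%), 7708 higher and 6340 lower, and 5890 changed at least 2-fold, 3586 up and 2304 down. A slide block gave 11233 genes. Higher calls made up 54.9% in the main values, 43.4% with quantile normalization (6016 of 13870), 32.9% with the authors' matrix (4471 of 13584), 28.2% with median centring (3562 of 12639) and 19.6% with spike-in scaling (2835 of 14480). The median of all genes was 0.084 in the main values, -0.343 with median centring, -0.225 with the authors' matrix, -0.538 with spike-in scaling, 0.123 with normexp and 0.131 without the filter.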

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

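The splits of pair differences, the test against a larger spread and the slide-block ratio were chosen only after the results they bear on had been seen, as were the settings that pair arrays within a clone, use spike-in scaling or leave out replicates 3 and 4. The E2 effect differed between the clones for 10 genes and for 5 gene lists. By the limma test of the difference, EGR3 had -3.57, RFPL1S -2.25, PGR -1.71, FOXC1 -1.21, SGK3 -1.13, SIAH2 -1.03 and CSMD3 1.01 (E2 effect in MKL1ΔN200 minus that in control cells). RFPL1S and CSMD3 were not well above background in MKL1ΔN200 cells, so an E2 effect could not be measured there for these genes. The median differences were -0.70 for the estrogen-induced, -0.41 for the ribosome biogenesis, -0.15 for the immediate-early, -0.06 for the luminal and 0.36 for the estrogen-repressed list. Only the estrogen-induced and ribosome biogenesis lists passed with both an estimated correlation and a slide block.

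When treatment was reassigned at random within each clone, 8 of 100 draws gave at least 10 genes, with 8721 in the highest other draw, so chance was not excluded in this form. A draw with so many genes points to a structure of the samples other than treatment. Keeping arrays of the same number within a clone together gave 260 genes (59 higher, 201 lower), and none of the 34 other ways to divide the 8 pair differences gave as many, with 110 in the highest of them, so 1 of 35 did. The median of the estrogen-induced list (-0.70) was also matched by 1 of 35, the real division, with 0.53 as the highest other. The share of 1 of 35 is the smallest that this test can give. These tests with pairs kept were chosen after the first had been seen, so they argue against chance but do not exclude it.

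Fewer genes passed for E2 in MKL1ΔN200 cells (0 in limma, 506 at an unadjusted p below 0.05) than in control cells (461). With the replicate block, 4 passed in MKL1ΔN200 cells and 1439 in control cells. Both E2 tests came from 1 fit with a shared spread per gene. The spread was not larger in MKL1ΔN200 cells. A gene's median SD was 0.185 under vehicle and 0.195 under E2 there, against 0.235 and 0.242 in control cells. The shared spread thus tends to favour calls in control cells, the clone with the larger spread. With only the arrays compared in the fit, 86 genes passed in control and 0 in MKL1ΔN200 cells, with fewer arrays to estimate the spread. A larger spread alone would leave the effects at full size. For 151 genes changed 2-fold in control pairs 1 and 2, the median effect was 1.36 in control pairs 3 and 4 and 0.15 in MKL1ΔN200 cells, a ratio of 0.11. An additive shift between slides was weighed with slide as a block, where the estrogen-induced list had medians of 1.01 in control and 0.20 in MKL1ΔN200 cells, a ratio of 0.2. RNA of other cells was weighed in pairs 1 and 2, where the genes that differ by replicate number are lowest, with a ratio of 0.18 (1.23 against 0.22, 178 genes). These 3 ratios argue against a larger spread, an additive slide shift or RNA of other cells as the whole cause. The slide of the MKL1ΔN200 arrays was also weighed within slide 1, where the ratio was 0.28 (1.32 against 0.37, 185 genes). Each clone had a single array in 1 of its groups there, so that value does not decide it, and a slide effect other than an additive shift stays open. Whether the mutant or the 4.09-fold lower ESR1 accounts for the smaller effects was not tested, with 1 sub-clone for each genotype.

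For E2 in control cells, 3 of the 35 splits of the 8 arrays gave at least 461 genes, and the split of replicates 1 and 2 against 3 and 4 gave 6532, so chance was not excluded over all splits. Among the 8 splits that part every same-numbered pair, the highest other gave 0 genes, and with the replicate block the real split gave 1439 and the highest other 0. The split of replicates 1 and 2 against 3 and 4 thus points to a structure of the samples that treatment does not share. In MKL1ΔN200 cells all 35 splits gave at least the real count of 0, with 201 for replicates 1 and 2 against 3 and 4, and the replicate block gave 4 against 0.

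Among 402 sets of 4 values tested for a sample far from the others of its group, 25 (6.2%) passed Dixon's bound, where chance gives about 1 in 20. The numbers here are the gap over the range, followed by log2 levels. In control vehicle samples, replicate 1 stood apart for AREG (0.932; 0.38 against -1.16 to -1.05), IFIT1 (0.913; -2.11 against -0.01 to 0.19) and CCND1 (0.894; 2.58 against 2.38 to 2.40). Replicate 2 stood apart for NOP16 (0.91; 3.35 against 3.61 to 3.63) and replicate 4 for KLF4 (0.902; 0.57 against 0.29 to 0.32). In control E2 samples, replicate 1 was lowest for EGR3 (0.867; -1.23 against -0.16 to 0.01) and NOLC1 (0.866; 3.27 against 3.75 to 3.83), and replicate 4 for SPDEF (0.869; 3.69 against 4.00 to 4.04).

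In MKL1ΔN200 vehicle samples, replicate 1 was lowest for KRT13 (0.85; 0.74 against 1.59 to 1.74) and CA14 (0.904; 4.98 against 5.97 to 6.07), and it was lowest for both under E2 too (0.926 and 0.93; 0.81 against 1.65 to 1.72, and 4.86 against 5.91 to 5.98). Replicate 4 was lowest for AREG under vehicle (0.847; 4.81 against 5.66 to 5.82) and E2 (0.864; 4.95 against 5.72 to 5.84). Under vehicle, replicate 2 was highest for TAGLN (0.901; 6.38 against 5.95 to 5.99) and WDR12 (0.884; 4.21 against 3.69 to 3.75), replicate 3 for IL1R1 (0.861; -1.68 against -3.88 to -3.57), and replicate 4 was lowest for POLR1B (0.883; 0.22 against 0.36 to 0.38). Under E2, replicate 4 was lowest for FOS (0.883; 0.01 against 0.32 to 0.37) and SESN2 (0.886; 0.02 against 0.36 to 0.41), replicate 3 for CXCL12 (0.838; -0.20 against 0.11 to 0.17), and replicate 1 was highest for PHGDH (0.859; 1.30 against 0.75 to 0.83).

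MKL1ΔN200 vehicle replicate 4 had 59.1% of probes well above background against 53% to 54% (0.836). MKL1ΔN200 E2 replicate 2 had a spike-in mean of 10.81 against 10.225 to 10.318 (0.841) and 395 spots marked as not uniform against 1 to 8 (0.982).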

How the results depend on the processing

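Spike-in scaling, keeping outlier spots, leaving out replicates 3 and 4 or MKL1ΔN200 E2 replicates 2 and 4, and pairing within a clone were tests chosen after the results were seen. The counts of both clone comparisons stayed within 1.5 times under every setting except a fold minimum of 2, which left 5319 genes under vehicle, 5890 under E2, and 114 for E2 in control cells. For E2 in control cells (461), the count was 1439 with the replicate block, 2698 with pairing within a clone, 228 with a slide block, 156 with median centring, 162 with spike-in scaling, 86 with only the control arrays fitted and 3 without replicates 3 and 4, where fewer samples were left. For E2 in MKL1ΔN200 cells (0), it was 4 with the replicate block, 9 with pairing within a clone, 2 with the authors' matrix, and 1 with the filter over all arrays and with trend and robust priors. For the difference of the E2 effects (10), it was 87 with the replicate block, 260 with pairing within a clone, 6 with the filter over all arrays, 1 with a slide block and 0 without replicates 3 and 4 (1718 at an unadjusted p below 0.05 in the main limma values). Leaving out each array gave 283 to 502, 0 to 1, 11205 to 11895, 12657 to 14075 and 8 to 17 genes in the 5 comparisons.

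The share of control-cell calls with the same sign in MKL1ΔN200 cells (89.2% of 461) was 63.5% of 156 with median centring, 63% of 162 with spike-in scaling, 78.9% of 2698 with pairing within a clone, 79.8% of 228 with a slide block, 84.2% of 1439 with the replicate block, 66.7% without replicates 3 and 4 (2 of 3 genes, too few to compare) and 79.2% to 92.4% without each array. Of 60 list tests, 29 passed in the main values, 10 with an estimated correlation, 26 and 36 with fry (on balance and mixed) and 27 to 32 without each array. Of the named genes' 183 calls tested, 167 passed, and 160 to 166 without each array. With a slide block these lists turned direction: MRTF-SRF for E2 in control cells (0.049), in MKL1ΔN200 cells (0.015) and in the difference (0.0026), immediate-early in MKL1ΔN200 cells (0.0011) and in the difference (0.43), and interferon in MKL1ΔN200 cells (0.033). The cell cycle list turned for E2 in MKL1ΔN200 cells without MKL1ΔN200 EtOH replicate 2 (0.0074) or E2 replicate 4 (0.00012), with adjusted p from 2.9e-06 to 0.55 over the single arrays left out. KRT18 turned to -0.26 and -0.28 between the clones under vehicle and E2 with quantile normalization, and to -0.50 under E2 with spike-in scaling. The cause was not tested for any of these. The slides held unlike replicate numbers in each group, so a slide block can also shift genes that follow the replicate number. With it, the mesenchymal list, with 7 such genes among 18, had E2 medians of -0.45 in control and 0.42 in MKL1ΔN200 cells. These medians were -0.07 and -0.05 without it.

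Of the named genes' calls, 16 were lost with a slide block, 16 with median centring, 17 with spike-in scaling, 40 without replicates 3 and 4 and 54 over all single arrays left out, where 1482 were the same. The replicate block gained the calls of ESR1 and CCND1 for E2 in control cells, PGR for E2 in MKL1ΔN200 cells and KRT18 between the clones under vehicle, and lost the luminal list between the clones under vehicle. For E2 in MKL1ΔN200 cells it also called MYB (0.0028) and NXNL2 (0.024). Scan was not tried apart from slide, because each slide was scanned as its own batch. Signal over background limits the low genes: the lowest signal well above background was -5.89 to -4.79 per array, and 784 genes called between the clones under vehicle were dim on all arrays of 1 clone, so their folds are bounds.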

Other observations

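The lists of adhesion, desmosome, antigen presentation and other genes named here, the slide test of the replicate-number genes, both keratin tests and the even splits were chosen after the results were seen. Genes of cell adhesion were higher in MKL1ΔN200 cells. Of 19 integrin and matrix adhesion genes, 14 were higher under vehicle and none lower (median 1.81, camera adjusted p = 1e-04, but adjusted p = 0.16 with an estimated correlation), and 14 under E2 (1.71, adjusted p = 0.00031, but adjusted p = 0.16 with an estimated correlation). ITGA1, the integrin alpha-1 chain, was higher by 9.23, ITGB3 by 4.69, the actin crosslinker gene ACTN1 by 4.13 and the laminin gene LAMB1 by 3.11. Of 14 desmosome and cornified envelope genes, 10 were higher and 1 lower under vehicle (median 0.90, adjusted p = 0.048, but adjusted p = 0.96 with an estimated correlation), among them DSC2 (3.19), PKP1 (2.54) and the protease gene KLK6 (3.86). Under E2, 10 were higher and none lower (1.07, adjusted p = 0.036, but adjusted p = 0.96 with an estimated correlation).

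Of 15 antigen presentation genes, 8 were higher and 1 lower under vehicle (median 0.97, adjusted p = 0.0097, but adjusted p = 0.96 with an estimated correlation) and under E2 (1.05, adjusted p = 0.025, but adjusted p = 0.96 with an estimated correlation). They included the peptide transporter gene TAP1 (4.65), the proteasome subunit gene PSMB9 (3.71) and HLA-B (1.66), beside the higher interferon-response genes. In the epidermal growth factor family (4 higher, 1 lower of 9, adjusted p = 0.48) the ligand genes BTC (5.08) and HBEGF (4.14) were higher and the receptor gene ERBB4 lower (-1.16). HBEGF is also among the genes that differed by replicate number. No shift was called under vehicle for cholesterol synthesis (4 higher, 8 lower of 18), glycolysis and hypoxia (8 higher, 2 lower of 18), estrogen receptor cofactors (3 higher, 6 lower of 16), YAP and TEAD targets (5 higher, 1 lower of 17), skeletal and heart muscle genes (4 higher, 4 lower of 11) or oxidative phosphorylation (7 higher, 5 lower of 19). Oxidative phosphorylation genes had a median of -0.04 for E2 in MKL1ΔN200 cells (adjusted p = 0.041, but adjusted p = 0.96 with an estimated correlation).

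The 163 genes that differed by replicate number, 132 of them with a symbol, were chosen on control arrays. Their median rose with the number in MKL1ΔN200 arrays too, under both treatments. Of the 163, 123 were low in MKL1ΔN200 replicate 1, and not every member moved alike. CALD1 had vehicle means of -0.75 in control and 5.27 in MKL1ΔN200 cells, and PLS3 had 0.54 and 5.76. A difference between slides was argued against, since control vehicle replicates 3 and 1, both on slide 1, differed by a median of 4.76. RNA of another kind of cell present in different shares would add 1 fixed profile, so the added signal of replicate 4 over replicate 3 would be nearly the same for all genes. In MKL1ΔN200 arrays, 89.4% of the 123 set genes low in replicate 1 lay within 1.5-fold of the median ratio of 2.41, as such an admixture would give. The share was 17.9% of other genes. Those were not chosen to differ between replicates, so this contrast does not bear on the cause. A culture state shared by samples of the same number was not tested and stays open.

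Signal of KRT14, KRT16 and KRT17 appeared in MKL1ΔN200 cells on all 8 arrays and on no control array. Cells of a basal layer mixed into the cultures would also bring KRT5, KRT6A, KRT6B, TP63 and DSG3, but 0 of these 5 were well above background on all 8 MKL1ΔN200 arrays, which argues against them. KRT5, KRT6A, KRT6B and DSG3 were so on 0 of the 8, while TP63 was on 6 of the 8 and on 3 of the 8 control arrays (mean level -4.25 against -5.55). All 5 probes of the 3 keratins were well above background on the 8 arrays, which cross-hybridisation between similar keratins could also give. Which of the 3 genes was expressed therefore cannot be told apart here. Induction of these keratins in the MKL1ΔN200 sub-clone stays a hypothesis.

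Between the clones, 1 of 35 splits of the 8 vehicle arrays gave as many genes as the real one (12156, against 1 in the highest other), and 1 of 35 splits of the 8 E2 arrays did (14048, against 1), so chance was excluded for both. Over all splits, the number of shifted lists did not exclude chance: 22 of 35 splits shifted at least 5 of 12 lists for E2 in control cells (9 in the highest other), 10 of 35 at least 4 in MKL1ΔN200 cells (6), 10 of 35 at least 7 between the clones under vehicle (8), 7 of 35 at least 9 under E2 (10), and 58 of 100 draws at least 5 for the difference of the E2 effects (10). Among the 8 splits that part every same-numbered pair, the 7 others shifted 0 to 4 lists for E2 in control cells, 0 to 3 in MKL1ΔN200 cells, 1 to 7 between the clones under vehicle and 0 to 9 under E2. These 8 splits are too few for a share under 0.05. A split with 3 arrays of 1 group on a side keeps part of the real difference, so the count over all 35 can overstate chance. Among the 18 even splits, with 2 arrays of each group on each side, 11 shifted as many lists as the real one for E2 in control cells (7 in the highest), 1 in MKL1ΔN200 cells (5), 3 between the clones under vehicle (8) and 0 under E2 (8). The median of the estrogen-induced list for E2 in MKL1ΔN200 cells (0.24) was reached by 3 of 35 splits (0.29 in the highest other), so chance was not excluded for it alone. Among the 8 splits that part every same-numbered pair, the 7 others gave -0.08 to 0.13. The share of control-cell calls with the same sign in MKL1ΔN200 cells (89.2%) was reached by 1 of 35 splits, the real one, with 87% as the highest other.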
